A study of Mus musculus with 4 samples.

How the data were processed

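Regulatory T cells (Tregs) were sorted from spleen and lymph nodes of male mice, 6 to 8 weeks old, that carried a Foxp3-driven red fluorescent protein with Cre, a YFP reporter at the Rosa locus and floxed alleles of Mll1, the histone methyltransferase gene whose mouse symbol is Kmt2a. Per the labels' protocols, CD4 cells were enriched with magnetic beads, 300000 Tregs per population were sorted at a purity above 95%, and RNA was made into libraries with a NEBNext Ultra kit. RFP-positive cells with YFP carried the Mll1 knockout label, and RFP-positive cells without YFP carried the wild-type label. Each group had 2 libraries, and the titles gave the same 2 mouse numbers to both groups. The labels do not say whether a number stands for a single animal or a pool, so "mouse 1" and "mouse 2" below are these numbers.

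Per the submitters' processing notes, HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and DESeq2 1.16.1 were used with the mm10 build, whereas the series' design text named DEGSeq 1.16.1 with Benjamini-Hochberg adjustment. The annotation release, the strand setting and the treatment of reads with several matches were not given in the sources used here. The deposited signal values were gene read counts that the authors had divided by a size factor per library. The authors' log2 fold changes were YFP-positive over YFP-negative. The authors' p-values and adjusted p-values came from their own test.

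The table held 282 genes, and each had an adjusted p-value under 0.05 and an absolute log2 fold change above 1 in the authors' columns. It is therefore a list of selected genes and not a background. The p-values and adjusted p-values in the authors' deposited table implied 14239 tested genes, and 3 ranks up to the last listed gene were not used here. Every value was a whole multiple of a step, within 0.001 reads, in 100% of the 282 values of each library. Reads and size factors here are inferred from this step, and few values were low enough to check the step closely (40, 32, 18 and 13 values of up to 20 reads in YFP-positive 1 and 2 and YFP-negative 1 and 2). The steps gave size factors of 0.962 and 0.943 for YFP-positive mice 1 and 2, and of 1.02 and 1.11 for YFP-negative mice 1 and 2. The listed genes held 196337, 205521, 329350 and 315764 reads in these libraries, in the same order, with medians of 169.5, 188.5, 320 and 347 reads per gene. These sums are not the libraries' depth, which a table of selected genes does not give. Counting precision was lowest for the 27 genes with a mean under 50 reads.

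A count model had been chosen before the data were examined, for a table of raw counts. Because the table held selected genes as normalized counts, with too few low values to rely on the inferred reads, limma 3.58.1 in R 4.3.3 was used instead, on log2(value + 1), with a variance trend and Benjamini-Hochberg adjustment over the 282 genes. Fold changes on this scale understate the change of low genes. The variance trend was chosen after the unit was known. The prior variance was estimated from genes selected on these same libraries, so the calls describe the list and are not independent evidence for it. The fit had no block for the mouse. The libraries were paired by mouse number, on the assumption that a number marks the same source in both populations. Deviations of the mouse 1 libraries from their group means correlated across the 282 genes (Pearson's r = 0.395, Spearman's rho = 0.411), although genes are not independent replicates. A second fit had the mouse as a block.

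The limma step was tested on simulated data for this comparison, with 282 genes of which 200 were changed. It called 4.88% of 82 unchanged genes, 86.2% of 65 genes with a log2 change of 1 and 100% of 58 and 77 genes with changes of 2 and 3, with 0 calls in the wrong direction. The simulation gave all genes the same dispersion, and had no mouse effect and no selection of genes. These rates need not hold for the deposited values.

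The 32 gene lists were fixed before the data were examined. Ly6c1 had been placed on both the activated and the resting Treg list. With no background in the table, no enrichment was tested, and a list's members were counted by direction. For the 8 lists with at least 3 members, a two-sided Fisher's exact test compared directions with the rest of the table, with Benjamini-Hochberg adjustment over the 8 lists. This test was chosen after the table's content was seen. It treats genes as independent, so its p-values do not measure the spread between mice.

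The named genes followed a rule fixed before the data were examined. They were the 12 protein-coding genes with the largest rise and the 12 with the largest fall in the authors' log2 fold change, with a mean of at least 50 reads and the same direction in both mice. Up to 4 members of each biology list and up to 3 members of each other list were added. Numbered gene models, pseudogenes and receptor segments were left out of the largest changes, and 5 numbered models were removed this way. The rule gave 50 genes, some of which are not reported here. Kmt2a and Foxp3 were also to be reported and were not analysed here, so these values do not check the deletion. Other genes named in the text were chosen after their values were seen, unless they are members of a fixed list.

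Gene identifiers and coordinates are those of the deposited table, on mm10. Of the 282 genes, 273 matched GENCODE release M21 by identifier and 9 were unnamed transcript models. Longest transcripts of the 273 genes were searched against all transcripts with BLAST+ 2.17.0, and a gene was called shared when matches at 95% identity or more covered at least 50% of it. Shared genes numbered 25, of which 10 were higher and 15 lower. Genes that overlap or share sequence are uncertain, since the authors' counting could split their reads. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

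Alternatives were a pseudocount of 0.1, a mean of at least 50 reads, the mouse block, each library left out in turn, each mouse alone, and an adjusted p-value under 0.001 in the authors' column. A fit without the variance trend, adjustment over 14239 genes, list tests without Ly6c1 or on fewer genes, and other settings of the neighbour test were added after seeing the data.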

Results

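RNA was sequenced from 4 libraries of mouse regulatory T cells (Tregs), the CD4 T cells that restrain immune responses. RFP marked Foxp3-expressing cells, and YFP from the Rosa reporter marked those in which Cre had acted. Of the 4 libraries, 2 came from YFP-positive Tregs labelled as Mll1 knockout and 2 from YFP-negative Tregs labelled as wild type, 1 of each under mouse numbers 1 and 2, which the labels do not define as single animals or pools. The deposited table listed 282 genes as normalized counts, and its listed genes held, by reads inferred from the values, between 196337 reads in YFP-positive mouse 1 and 329350 reads in YFP-negative mouse 1. The targeted gene, Kmt2a, and Foxp3 were not analysed here, so the values below do not check the deletion.

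The comparison of YFP-positive with YFP-negative Tregs asks which genes differ in Tregs that lack the methyltransferase MLL1, with regard to their activation and specialization. Ly6c2, Igfbp4, Bcl2 and Bach2 were among the genes that were higher in YFP-positive Tregs. Klrg1, Tigit, Penk, Gzmb, Il1rl1, Il18rap, Cxcr3, Cxcr6 and Ccr10 were among those that were lower. Of the 282 listed genes, 86 were higher and 196 (69.5%) were lower in YFP-positive Tregs. In the authors' deposited table, the median log2 fold change was 1.79 among the higher genes and -1.89 among the lower genes.

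The 2 groups did not overlap in 282 of 282 genes, whereas chance gives 33.3% for 2 libraries against 2, and the direction was the same in both mice in 282 of 282. By limma with Benjamini-Hochberg adjustment, all 282 genes passed an adjusted p of 0.05. The genes had been selected on these same libraries, so neither count is independent evidence.

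**Figure D1:**
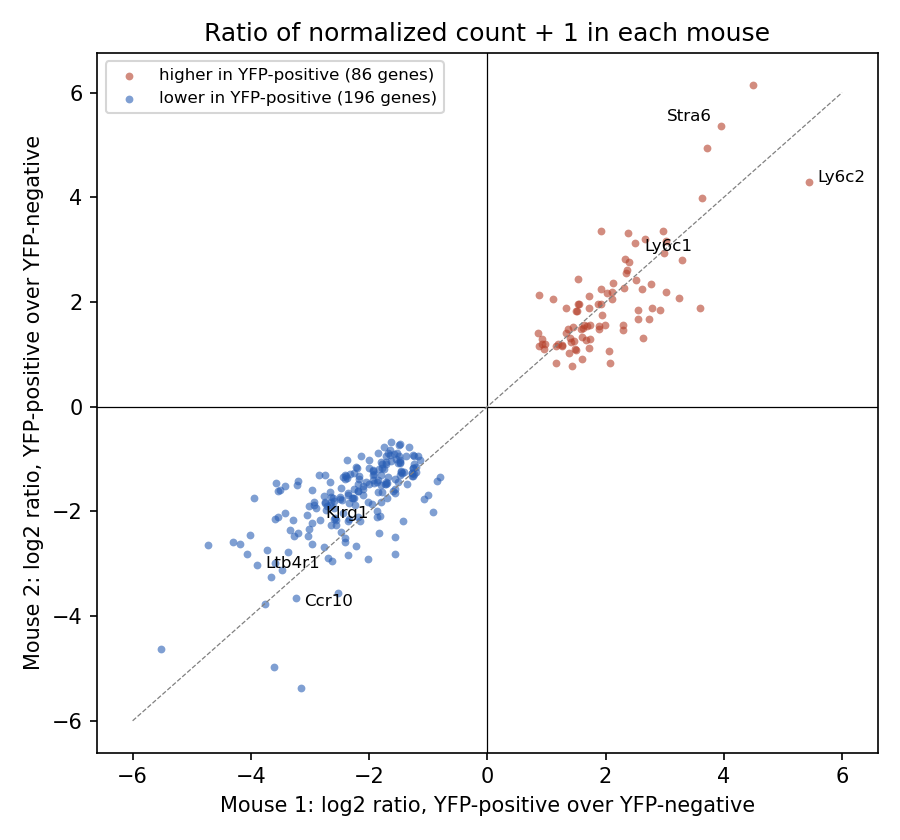
Each point is 1 of the 282 listed genes. The x axis gives the log2 ratio of YFP-positive over YFP-negative normalized counts (+ 1) in mouse 1 and the y axis gives it in mouse 2, with 86 higher genes in red, 196 lower genes in blue and equal ratios on the dashed line. All points lie in the quadrants where both mice have the same direction.

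The largest rise among the named genes was that of Ly6c2 (ENSMUSG00000022584, chromosome 15, 75108158 to 75111970, minus strand), which encodes a Ly6C surface antigen. Its normalized count was 577 ± 144 in YFP-positive and 19.1 ± 6.14 in YFP-negative Tregs (SD, n = 2 each). This is a 30.3-fold difference, and limma gave a log2 fold change of 4.86 ± 0.46 (SE), adjusted p = 3.39e-12. That p leans on a variance trend fitted to the selected genes. The limma adjusted p was 1.88e-05 without the trend and 0.00195 with the mouse as a block. The neighbouring Ly6c1 (chromosome 15, 75044018 to 75048830) rose by 2.82 ± 0.35 on the log2 scale, from 867 ± 254 to 5979 ± 66.6 normalized counts. Matches to other transcripts covered 97.8% of the Ly6c1 transcript, with Ly6c2 as the closest, and 45.9% of the Ly6c2 transcript, so the split of reads between the 2 genes is uncertain. Stra6, which encodes a retinol transporter, was counted at 158 ± 11.2 against 6.25 ± 5.02, with 10 and 3 reads in the YFP-negative libraries, a log2 fold change of 4.66 ± 0.62. Gata1, a transcription factor gene of the erythroid lineage (chromosome X, 7959260 to 7978071), rose by 2.45 ± 0.36, from 137 ± 6.31 to 756 ± 109. Ncf1, which encodes a subunit of the phagocyte NADPH oxidase, rose by 3.05 ± 0.51, and Sorcs2 rose by 3.10 ± 0.55. Fsd1l, Arhgap20 and Tgm2 rose by 2.38 ± 0.54, 2.15 ± 0.50 and 2.09 ± 0.53. Without YFP-negative mouse 1, Tgm2 no longer passed (log2 fold change 1.80, limma adjusted p = 0.0540, against 0.000349 to 0.0284 under the other alternatives).

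Among named genes with a mean of at least 50 reads, the largest falls were those of Ltb4r1 and Ccr10. Ltb4r1, the leukotriene B4 receptor gene (chromosome 14, 55765962 to 55768494), was counted at 14.7 ± 6.14 in YFP-positive and 166 ± 4.76 in YFP-negative Tregs (SD, n = 2 each), and its log2 value fell by 3.47 ± 0.54. Ccr10, a receptor gene of skin and mucosal homing (chromosome 11, 101172997 to 101175443), was counted at 8.91 ± 2.11 against 106 ± 1.12, and fell by 3.45 ± 0.60 on the log2 scale. The log2 fold changes of Slc15a3, Slc24a3, Pkhd1l1 and Fgf16 were -3.24 ± 0.54, -3.08 ± 0.47, -3.04 ± 0.59 and -2.87 ± 0.59. Cobll1 fell by 2.85 ± 0.58 and Tmem51 fell by 2.81 ± 0.61. Both listed MLL1 targets of blood cells in the table, out of 20, were lower, against 69.5% of all 282 genes. With so few members their direction was not tested, and the other targets have no value here. Pbx3, a homeobox partner of Hox proteins, fell by 2.76 ± 0.58, and Cdkn2c, a cyclin-dependent kinase inhibitor gene, fell by 2.36 ± 0.40. Mlf1 fell by 2.31 ± 0.60, and this rested on YFP-negative mouse 1. Without that library its log2 fold change was -1.27, with limma adjusted p = 0.110, and without YFP-positive mouse 2 adjusted p = 0.0531, against 0.000594 to 0.0368 under the other alternatives.

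Of 30 activated and effector Treg genes, 14 were in the table, of which 13 fell and 1 rose. Klrg1, an inhibitory receptor gene of terminally differentiated Tregs (ENSMUSG00000030114, chromosome 6, 122270596 to 122282882), was counted at 622 ± 177 against 3275 ± 606 (SD, n = 2 each), a log2 fold change of -2.41 ± 0.34 with limma adjusted p = 2.08e-07. The limma adjusted p was 0.000464 without the variance trend and 0.00217 with the mouse as a block. Penk, the proenkephalin gene, fell by 2.49 ± 0.42, and Havcr2, which encodes TIM-3, fell by 2.79 ± 0.53. Tigit fell by 2.30 ± 0.36 and Gzmb fell by 1.87 ± 0.34. The other members that fell were Il1rl1, Prdm1, Pdcd1, Tnfrsf9, Icos, Ebi3, Batf and Tnfrsf1b. When limma p was adjusted over 14239 genes, Tnfrsf9, Batf, Icos and Tnfrsf1b did not pass (adjusted p = 0.0890, 0.177, 0.235 and 0.469). Icos and Tnfrsf1b also did not pass with the mouse as a block (limma adjusted p = 0.0770 and 0.0700), nor did Tnfrsf1b without YFP-positive mouse 1 (0.0522) or YFP-negative mouse 1 (0.0709). The member that rose was Ly6c1, which is also on the resting list. Against the direction of the other listed genes, a two-sided Fisher's exact test gave p = 0.0712 and adjusted p = 0.285. With Ly6c1 left out of both lists, a choice made after its values were seen, the same exact test gave adjusted p = 0.0466 for 13 of 13 members lower.

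Of 22 resting and central Treg genes, 5 were in the table, and 5 of 5 rose (two-sided Fisher's exact test of direction, p = 0.00243, adjusted p = 0.0194). With Ly6c1 left out of both lists, 4 of 4 rose and the same exact test gave adjusted p = 0.0466. Igfbp4 rose by 1.66 ± 0.37, and Bcl2, the anti-apoptotic gene, rose by 1.45 ± 0.38. Bach2, a transcriptional repressor gene, rose by 1.26 ± 0.35, and Ly6c1 is also a member. Without YFP-positive mouse 1, the members that passed numbered 3. Igfbp4 then had limma adjusted p = 0.0533 and Bcl2 had 0.0518, against at most 0.0301 and 0.0455 under the other alternatives. Without YFP-negative mouse 1, the log2 fold change of Bcl2 was 0.94. Among the 62 lower and 34 higher genes under 0.001 in the adjusted p column of the authors' deposited table, 2 resting members were left, and the exact test gave adjusted p = 0.609. The study's own selection chose both sets of members on these samples, so their directions are not independent evidence. In the same libraries Igkc, the immunoglobulin kappa constant gene and the 1 listed B cell marker in the table, fell by 2.26 ± 0.34, from 1287 ± 305 to 264 ± 22.2.

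**Figure D2:**
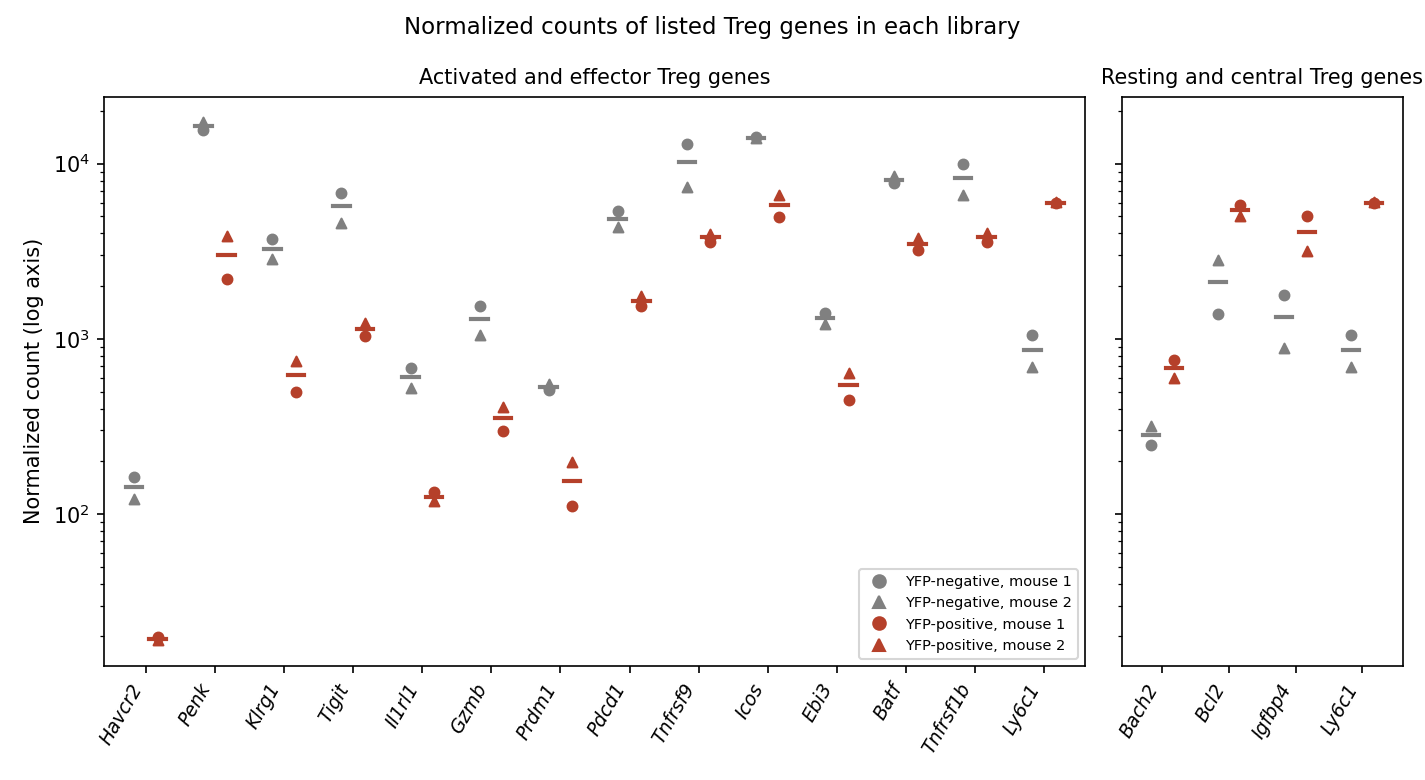
Normalized counts (log axis) of the activated and effector members (left) and 4 of the resting and central members (right) in each library, with circles for mouse 1, triangles for mouse 2 and bars at the mean of the 2 mice. YFP-positive values (red) lie below YFP-negative values (grey) for 13 of the 14 genes on the left and above them for the 4 genes drawn on the right, where Ly6c1 is drawn in both panels.

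Members of the helper T cell lists in the table were all lower. The lists share genes, so their counts are not separate evidence. Il1rl1, Batf, Pdcd1 and Icos are also on the activated list, and Maf is on both the Th2-type and the Th17-type list. Of 21 genes of the Th1-type list, 6 were in the table and 6 fell, among them Ifng, the interferon-gamma gene (log2 fold change -2.41 ± 0.38), Cxcr3 (-2.23 ± 0.38), Ccl5 (-1.89 ± 0.34) and Tbx21, which encodes T-bet (-1.60 ± 0.43). Of 15 genes of the Th2-type list, 3 fell, namely Il1rl1, which encodes the interleukin-33 receptor (-2.24 ± 0.37), Maf (-1.60 ± 0.34) and Gata3 (-1.09 ± 0.35). Of 15 genes of the Th17-type list, 6 fell, among them Ltb4r1, Rora (-1.90 ± 0.39) and Ahr (-1.48 ± 0.36). Of 16 follicular regulatory T cell genes, 6 fell, among them Sostdc1 (-3.46 ± 0.72), Il1r2, the interleukin-1 decoy receptor gene (-1.86 ± 0.38), Angptl2 (-1.80 ± 0.35) and Pdcd1 (-1.56 ± 0.36). Sostdc1 was low, with mean normalized counts of 4.21 in YFP-positive and 55.2 in YFP-negative Tregs. With a mean of at least 50 reads, 5 follicular members were left, and the exact test of direction gave adjusted p = 0.435. None of the 4 lists passed the two-sided Fisher's exact test of direction, with adjusted p = 0.292 for the Th1-type, Th17-type and follicular lists and 0.635 for the Th2-type list. Rora did not pass without YFP-positive mouse 2 (limma adjusted p = 0.0742, against at most 0.0412 under the other alternatives), and its log2 fold change was -1.17 without YFP-negative mouse 1. Tbx21 did not pass without YFP-negative mouse 1 (limma adjusted p = 0.0810). Gata3 did not pass when limma p was adjusted over 14239 genes (adjusted p = 0.154, against at most 0.0428 under the other alternatives).

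Of 26 chemokine receptor and homing genes, 7 were in the table, of which 6 fell and 1 rose (two-sided Fisher's exact test of direction, p and adjusted p = 0.679). Cxcr6 fell by 2.34 ± 0.34, from 2164 ± 156 to 446 ± 193 normalized counts (SD, n = 2 each), and Gpr15, a homing receptor gene of the large intestine, fell by 2.13 ± 0.35. Ccr2 fell by 1.90 ± 0.34 and Gpr183 fell by 1.25 ± 0.37, although Gpr183 did not pass when limma p was adjusted over 14239 genes (adjusted p = 0.0844), and Cxcr3 and Ccr10 were given above.

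The receptor genes Il1r2, Il1rl1, Il18r1 and Il18rap lie on the plus strand of chromosome 1 between 40074079 and 40551705, and each was lower in YFP-positive Tregs. Il1rl1 (40429570 to 40465415) and Il18r1 (40465552 to 40500854) are 137 bases apart. The log2 fold change was -1.26 ± 0.34 for Il18r1 and -2.27 ± 0.44 for Il18rap, which with Il18r1 encodes the interleukin-18 receptor. Without YFP-positive mouse 1, Il18r1 did not pass (limma adjusted p = 0.0748). Without YFP-negative mouse 2, Il18rap did not pass (limma adjusted p = 0.0865, against 1.17e-07 to 0.0466 under the other alternatives).

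**Figure D3:**
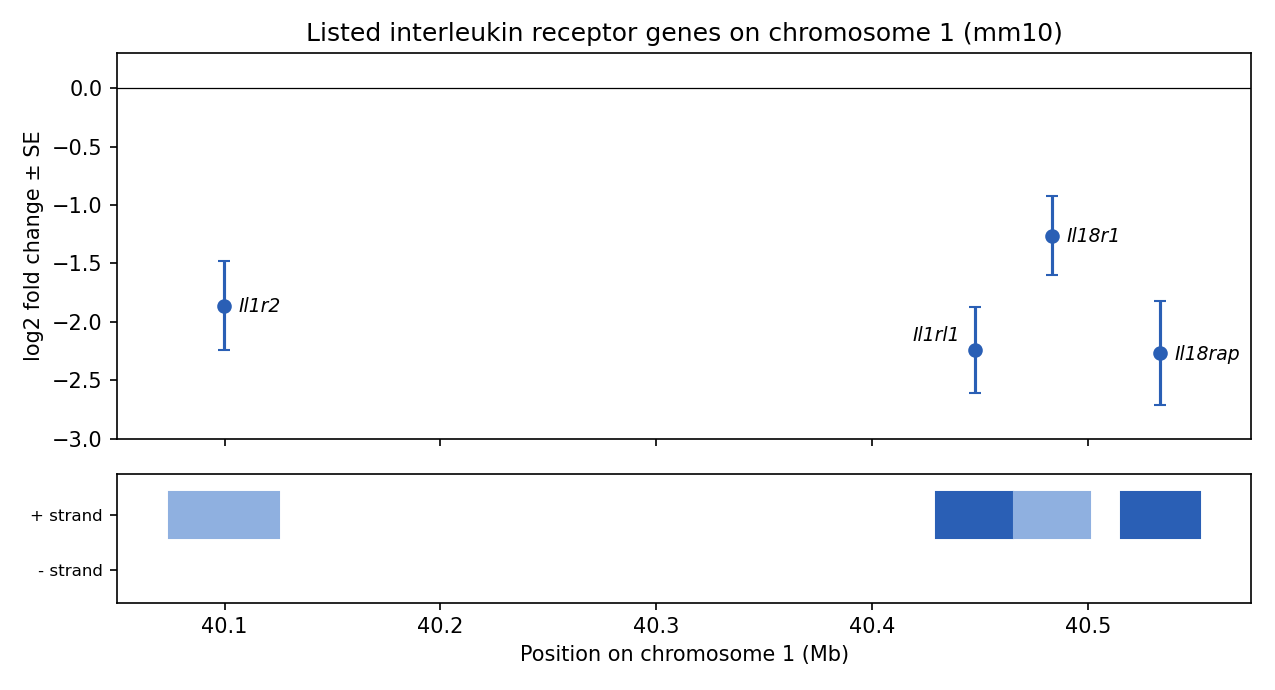
The upper panel gives limma's log2 fold change ± SE (YFP-positive over YFP-negative) of the 4 receptor genes at their position on chromosome 1 (mm10, in Mb). The lower panel draws the genes to scale on their strand in alternating shades, and all 4 values lie below 0.

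Of the listed genes, 18 carried a transcription factor family in the deposited table, of which 14 were lower and 4 higher. The family label was taken as deposited and was not checked, so a labelled gene need not encode a transcription factor. The higher genes were Gata1, Jun, Bach2 and Cers6, of which Cers6 did not pass without YFP-negative mouse 1 (limma adjusted p = 0.0539). The lower genes included Id2, which was counted at 2277 ± 5.09 against 8263 ± 2127 (log2 fold change -1.83 ± 0.39), Prdm1, which encodes Blimp-1 (-1.84 ± 0.37), and Batf (-1.22 ± 0.40), which did not pass over 14239 genes as given above. This split was not tested.

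The remaining lists had few members in the table. Gpr83, the 1 member of 24 Treg identity genes, rose by 1.60 ± 0.36, from 1597 ± 219 to 4851 ± 837. Of 40 interferon-stimulated genes, Oas2 rose by 2.61 ± 0.59 and Gbp2 rose by 1.09 ± 0.34, and Gbp2 did not pass when limma p was adjusted over 14239 genes (adjusted p = 0.136, against at most 0.0435 under the other alternatives). Jun, the 1 immediate early gene in the table, rose by 1.52 ± 0.39. Gzma, a granzyme gene on both the CD8 T cell and the natural killer cell list, fell by 3.23 ± 0.58, with a log2 fold change of -2.13 without YFP-positive mouse 1. Car2 of the erythroid and platelet list fell by 1.81 ± 0.43 and did not pass without YFP-negative mouse 2 (limma adjusted p = 0.0664, against at most 0.0274 under the other alternatives). Pecam1 of the stromal and endothelial list rose by 1.21 ± 0.33. Of 14 naive conventional CD4 T cell markers, Igfbp4 and Bcl2 rose and Cd40lg, the CD40 ligand gene, fell by 1.33 ± 0.34 (two-sided Fisher's exact test of direction, adjusted p = 0.295). The other 14 lists had 0 members among the 282 genes. They were the Kmt2a target locus, MLL1 complex members, transforming growth factor and interleukin-2 signalling, T cell receptor signalling, proliferation, glycolysis, oxidative phosphorylation, plasma cells, monocytes and macrophages, dendritic cells, granulocytes and mast cells, mitochondrially encoded genes, ribosomal proteins and histones. A gene outside the list of selected genes has no value here, so these counts of 0 do not show that those genes were alike in both groups.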

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

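The settings without a variance trend, with adjustment over 14239 genes, of the list direction test and of the neighbour test were chosen after the results were seen. By limma, 282 of 282 genes passed with a pseudocount of 0.1 and without a variance trend, 255 of 255 with a mean of at least 50 reads, and 257 to 269 when 1 library was left out, where the lone library is assumed to vary like the other group. With the mouse as a replicate block, 279 passed (86 higher, 193 lower), and Icos and Tnfrsf1b were among the 3 that did not. Adjusted over 14239 genes, 236 passed (67 higher, 169 lower), since more tests were counted. None of these fits changed a gene's direction. In either mouse alone, a value with no test, 0 of the 50 named genes reversed and 39 stayed within 1 SE of limma's log2 fold change. That fold change is the mean of both mice's values, so part of this closeness was built in. The absence of reversals was fixed in advance. The groups did not overlap, and both mice had the same direction, in 282 of 282 selected genes. An adjusted p under 0.001 in the authors' deposited table left 34 higher and 62 lower genes. The direction of the activated list had adjusted p = 0.0466 by Fisher's exact test without Ly6c1 (0.0466 to 0.609 over its alternatives), and that of the resting list had 0.609 under the 0.001 threshold (0.0171 to 0.609), where fewer genes were tested. DESeq2, RLE or total count scaling, CPM filters, camera and fry were not run, because the table holds selected genes as normalized counts. Scaling to recovered library sizes was not run, since a table of selected genes does not give them. Low read numbers limit the 27 genes with a mean under 50 reads.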

Other observations

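All tests in this part were chosen after the results were seen, and the genes of the first paragraph were chosen after their values were seen.

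T cell receptor segments moved in both directions. The gamma constant gene Tcrg-C4 (chromosome 13, 19344558 to 19352756) was counted at 101 ± 43.9 in YFP-positive and 2.45 ± 3.47 in YFP-negative Tregs (SD, n = 2 each), a limma log2 fold change of 5.32 ± 0.78. Tcrg-C1 rose by 2.96 ± 0.48, with 70.1% of its transcript matched by other genes. Trav4n-4 fell by 5.07 ± 0.61, and 100% of its transcript matched other genes, Trav4d-4 among them. Lgals3, which encodes galectin-3, fell by 2.72 ± 0.43, and the log2 fold changes of the annexin genes Anxa1 and Anxa2 were -2.73 ± 0.55 and -1.55 ± 0.34. Those of the matrix metalloproteinase genes Mmp9, Mmp14 and Mmp25 were -2.49 ± 0.40, -2.03 ± 0.51 and -3.68 ± 0.75, whereas Mmp11 rose by 1.46 ± 0.41 but did not pass when limma p was adjusted over 14239 genes (adjusted p = 0.0528). Without YFP-positive mouse 1, the log2 fold change of Anxa1 was -1.80. The class II antigen-processing gene H2-Ob rose by 1.80 ± 0.33, and Ecm1 rose by 1.91 ± 0.36.

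In YFP-positive Tregs, 13 of the 14 listed activated genes in the table were lower and 5 of the 5 listed resting genes were higher, with adjusted p = 0.285 and 0.0194 in Fisher's exact test of direction, and 0.609 for both lists among genes with an adjusted p under 0.001 in the authors' deposited table. Conventional T cells in the YFP-positive sort would raise their own markers and lower Treg identity genes. Gpr83, the 1 listed identity gene in the table, rose instead (limma log2 fold change 1.60 ± 0.36), and Cd40lg, a listed conventional marker, had -1.33, whereas the other 2 listed conventional markers in the table rose, Igfbp4 by 1.66 and Bcl2 by 1.45. With markers going both ways and 1 of 24 identity genes in the table, this explanation stays open. Only the YFP-positive sort was considered. Whether the YFP-negative sort held cells other than Tregs was not tested. To lower the activated list by its median by dilution, 68.6% of the cells would have to lack these transcripts, and the labels give a sort purity above 95%. This contrast decides nothing. All listed genes had an absolute log2 fold change above 1, so any list of lower genes would need a large share. A common scaling factor per library would move all genes alike. Of the 18 distinct members of the 2 lists, the most that 1 common shift brought to within 2 SE of 0 was 13. That shift, of -1.90 in log2, took in all 13 lower activated genes and left the 5 resting genes. The binomial test of this count (p = 0.00101, although genes are not independent) decides nothing. Listed genes had an absolute log2 fold change above 1, so members of opposite direction could hardly share 1 shift. A shift of -1.90 would have lowered nearly all genes. Instead, 86 of the 282 listed genes rose. The authors' p-values and adjusted p-values implied rank 285 for the last listed gene among 14239 tested genes. These values argue against a scaling shift of that size as the cause of the activated genes' fall. A difference that follows the history of the reporter instead of the loss of Mll1 cannot be told apart from it, because 0 libraries had a recombined reporter and an intact Mll1 gene.

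Gm28437, a pseudogene on chromosome 1, was counted at 6120 ± 1794 in YFP-positive and 1358 ± 923 in YFP-negative Tregs (limma log2 fold change 2.33 ± 0.39). Its transcript matched the mitochondrial gene mt-Co3 over 100% of its length at 100% identity. A candidate explanation is reads of the mitochondrial genome counted at a nuclear copy, and the match to a mitochondrial transcript over 100% of its length is in line with it. No biological explanation was tested.

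Neighbouring genes of the table often moved in the same direction, as for Il1r2, Il1rl1, Il18r1 and Il18rap and for Cxcr6, Ccr1 and Ccr2. Of 48 pairs at most 500000 bases apart, 38 (79.2%) shared a direction, against 57.5% with directions shuffled over the genes (one-sided permutation test, p = 0.00222). Gaps of up to 100000 and 1000000 bases gave 18 of 19 pairs (p = 0.00053) and 58 of 77 pairs (p = 0.00138) by the same permutation test. Without genes of shared sequence and unnamed models the permutation p was 0.0202 (27 of 35 pairs), and without overlapping pairs as well it was 0.0253 (26 of 34 pairs). The 2 clusters named above, and 3 other pairs of genes, had been noticed before the test was chosen. Without them 26 of 36 pairs shared a direction (permutation p = 0.0481, not adjusted for the number of settings). This argues only narrowly against chance directions, in a set that still holds genes of shared sequence. Without those genes and unnamed models as well, the permutation p was 0.196 (17 of 25 pairs). Without overlapping pairs too it was 0.242 (16 of 24 pairs). In these smaller sets chance directions stay open, and reads shared between similar or overlapping genes stay open for the pattern. Read-through between close genes was not tested, and no biological explanation was tested.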
